A study of Mus musculus with 24 samples.

How the data were processed

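Bulk RNA-seq counts were analysed from 24 libraries of cells sorted from the lamina propria of the mouse small intestine. The labels place the libraries in 8 groups, 4 sorted populations (ILC1, NKp46, CCR6 and DN) in 2 genotypes (WT and DKO), with 3 libraries per group. Per the labels, the libraries were made from 10 ng of total RNA with an RNA integrity number above 8, amplified in 12 to 15 PCR cycles with a low-input SMARTer kit, and sequenced on a NovaSeq. The kit amplifies full-length cDNA, no molecular identifiers are named, and PCR copies of a molecule can therefore not be told apart from separate molecules.

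The deposited values are whole-number read counts per Ensembl gene, not normalized, as the values in the table show. The submitters' processing notes name the mm10 build, bcl2fastq, STAR 2.7.9a, Subread, featureCounts 2.0.3, Salmon 1.5.2, DESeq2 and R 4.1. Which of these tools made the count table, its strand setting, its treatment of reads that map to several places and the annotation release are not given in the sources used here. One title and its description differ in a letter of the population name, and both were read as NKp46. The table had 55774 rows. Of its Ensembl IDs 168 stood on more than 1 row, 455 rows in all, and 1 row per ID was kept, which left 55487 genes. Coordinates came from GENCODE mouse release 21 on GRCm38 (mm10), in which 55141 of the IDs were found, among them all 399 named genes. There were 0 columns of values left unused.

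Counts were normalized by the trimmed mean of M values, and genes were filtered on expression by group with edgeR 4.0.16 in R 4.3.3, which left 21286 genes. CPM values are counts per 1e6 counts with these factors. A quasi-likelihood model with robust dispersions was fitted to all 24 libraries with 1 mean per group, which left 16 residual degrees of freedom. The common biological coefficient of variation was 0.573. Every adjusted p given for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 21286 genes, and a gene is called at an adjusted p under 0.05. Standard errors were derived from the log2 fold change and its F statistic. The contrasts were DKO against WT in each population, each of the other WT populations against WT NKp46, the genotype effect in NKp46 minus that in each other population, and a test of any difference of the genotype effect among the 4 populations. The genotype contrasts share no libraries. Replicate numbers are shared between groups in the labels, which do not say that they mark an animal, so no pairing entered the main model.

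The genes named in the text follow a rule fixed before the data were examined. It takes the deleted genes, Vav1 and the sorting markers. It takes up to 8 genes each way per genotype contrast, 5 each way per WT contrast and 4 each way per difference of genotype effects. They are ranked by size of the log2 fold change among called genes. In the genotype and WT contrasts the libraries must not overlap and the higher group must reach 5 CPM. For differences of genotype effects any of the 4 groups must reach 5 CPM, and libraries may overlap. The rule also takes up to 4 members of each gene list per contrast by adjusted p, and up to 10 genes called in one direction in all 4 populations. Predicted genes, antigen receptor segments and sex-linked genes were left out of the size ranking. Where a group had 0 counts, the fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, levels are given without a fold. These floors cover counting error alone. Results of some genes that the rule takes are not reported here.

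Also before the data were examined, 26 lists with 484 members were fixed from general knowledge. They cover REV-ERB-repressed clock genes, clock output genes, ILC3 identity, type 1 and cytotoxic genes, LTi-like genes, NKp46 ILC3 genes, ILC2 genes, T cell genes, B cell and plasma cell genes, myeloid genes, epithelial genes, stromal and endothelial genes, glycolysis, oxidative phosphorylation, fatty acid and lipid metabolism, cholesterol synthesis, mitophagy and mitochondrial genes, proliferation, dissociation stress and immediate early genes, interferon-stimulated genes, NF-kB targets and negative regulators, apoptosis regulators, TGF-beta and tissue residency genes, inhibitory receptors, ribosomal proteins and sex-linked genes. Some genes stand on more than 1 list. Tox stands on the lists of ILC3 identity and of inhibitory receptors. Tbx21, Klrk1, Il2rb, Ccl4, Gzmb, Cxcr3 and Il18r1 of the NKp46 ILC3 list also stand on the type 1 and cytotoxic list. Results of those lists are therefore not separate from each other. Lists with at least 4 tested members were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The sex-linked list had fewer and was not tested. Each list was tested again with its correlation estimated from these libraries, and with fry. Counts of members called over all genes are accompanied by counts adjusted over the list alone. An ILC1-high and an ILC3-high gene set were taken from WT ILC1 against the mean of WT CCR6 and WT DN, so that no NKp46 library entered their choice.

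The procedure was tested on simulated counts drawn from the real means and library sizes with 200 of 21286 genes changed. For DKO against WT it recovered 38% of the 2-fold and 88% of the 4-fold changes in ILC1, 35% and 84% in NKp46, 50% and 94% in CCR6 and 47% and 92% in DN, with 2.04% to 3.82% false calls. Of 20 simulated lists in NKp46 the 1 changed list was called and 0 of the others. Changed genes were taken from those with a mean above 5 CPM, and each gene had 1 dispersion for all populations. The recovery rates thus do not cover less abundant genes or a spread that differs between populations. Genes were drawn independently of each other, so the simulated lists do not check camera for correlated lists. Real lists had estimated correlations of up to 0.64.

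Alternatives were another scaling (RLE), no filter and a stricter filter, DESeq2 1.42.0 and limma voom with a random block. Further ones were only the groups compared, a replicate block, each library left out in turn and other thresholds. The replicate block was the replicate number for DKO against WT, and genotype with number for the other contrasts. Added after the data were seen were counts thinned to the smallest library, the analyses without WT ILC1 library 2 in contrasts that do not use it, protein-coding genes alone and further settings for the list and overlap results. Adjusted p-values that DESeq2 gives as missing stayed missing. Tables were read with the package data.table (version 1.17.8) and pandas 2.3.3 (Python 3.11.15), and figures were drawn with matplotlib 3.10.9.

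Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart. Among the named genes, exons of Nr1d1 and Thra share 263 bases, Dbp and Sphk2 539, Bhlhe41 and Gm43909 1280, Pfkp and Pitrm1 748, Timp3 and Syn3 1733, Eps8l3 and 4933431E20Rik 964, Gstm5 and 4933431E20Rik 178 and Tox and Gm11802 260. Counts of near-identical copies (Bcl2a1b and Bcl2a1d, the Klra and Klrc families, Trbc1 and Trbc2, Slc6a20a and Slc6a20b, H2 genes and ribosomal proteins with processed pseudogenes) are uncertain in how reads were split between them.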

Results

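RNA was sequenced from 24 samples of innate lymphoid cells sorted from the lamina propria of the mouse small intestine. Innate lymphoid cells (ILCs) are tissue lymphocytes without rearranged antigen receptors. ILC1 make interferon gamma and depend on the transcription factor T-bet, and ILC3 make interleukins 17 and 22. The mice were 8 to 12 weeks old. Animals labelled DKO carried Cre recombinase under Vav1 control, which is active in blood cells, and floxed Nr1d1 and Nr1d2. Littermates with the floxed genes served as controls and are labelled WT. Nr1d1 and Nr1d2 encode REV-ERBα and REV-ERBβ, nuclear receptors that repress transcription within the circadian clock. The series title names ILC1 and subsets of ILC3 that lack REV-ERBs as its subject. The sorted populations are labelled ILC1, NKp46, CCR6 and DN. NKp46 is the natural cytotoxicity receptor encoded by Ncr1, and CCR6 is a chemokine receptor of lymphoid tissue inducer-like (LTi-like) ILC3. The label DN is not explained in the sources used here.

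Each of the 8 groups held 3 libraries. Total counts, in M (1e6 counts), ranged from 12.8 M to 84.4 M per library. They were 12.8 to 41.1 M in WT ILC1, 22.4 to 56.3 M in DKO ILC1, 29.2 to 48.9 M in WT NKp46 and 23.7 to 29.2 M in DKO NKp46. In WT CCR6 they were 51.6 to 84.4 M, in DKO CCR6 41.7 to 62.9 M, in WT DN 38.0 to 46.7 M and in DKO DN 40.7 to 66.7 M. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these libraries. That spread was estimated over all 8 groups together, not over the groups compared alone. Replicate pairs had Spearman correlations of log CPM over genes from 0.889 to 0.968, and no pair came within counting noise. The first principal component (20.0% of variance) set ILC1 apart from CCR6 libraries, and the second (9.57%) was above 0 in all 12 WT libraries and below 0 in all 12 DKO libraries. The third (8.24%) set apart WT ILC1 library 2, at -180 against -43.3 to 45.4 in the others. In that library 84.1% of counts lay in protein-coding genes, against 91.6% to 94.9% in the others. Levels below are mean CPM ± SD of 3 libraries, and fold changes are log2 ± SE from edgeR.

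The targeted genes were higher, not lower, in the libraries labelled DKO. Nr1d1 (ENSMUSG00000020889; GRCm38 chromosome 11, 98767932 to 98775333, minus strand, 8 exon blocks) measured 486 ± 28.5 CPM in DKO against 95.6 ± 42.2 in WT ILC1, 1061 ± 87.9 against 601 ± 56.4 in NKp46, 1500.1 ± 53.2 against 574 ± 30.9 in CCR6 and 1654 ± 150.1 against 425 ± 55.9 in DN. The log2 fold changes were 2.34 ± 0.21 (adjusted p = 8.8e-07), 0.82 ± 0.20 (adjusted p = 0.022), 1.39 ± 0.21 (adjusted p = 1.4e-04) and 1.96 ± 0.21 (adjusted p = 2.4e-06). Nr1d2 (ENSMUSG00000021775; chromosome 14, 18204054 to 18239127, minus strand) rose by 1.99 ± 0.37 in ILC1 (adjusted p = 0.0055), 1.55 ± 0.36 in CCR6 (adjusted p = 0.013) and 1.54 ± 0.36 in DN (adjusted p = 0.018). In NKp46 it was 129.6 ± 19.7 CPM in DKO against 64.5 ± 2.58 in WT, a difference of 1.01 ± 0.36 that missed the threshold (adjusted p = 0.13). Exons of Nr1d1 share 263 bases with Thra on the opposite strand, and Thra measured 13.4 to 14.9 CPM in WT and 22.1 to 51.5 CPM in DKO libraries. Vav1, whose control elements drive the Cre, differed by -0.04 to 0.02 in the 4 populations. The labels do not say which exons are deleted, and counts per gene cannot show a missing exon, so these values do not check the genotype labels. Every direction given here for DKO rests on the labels.

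**Figure D1:**
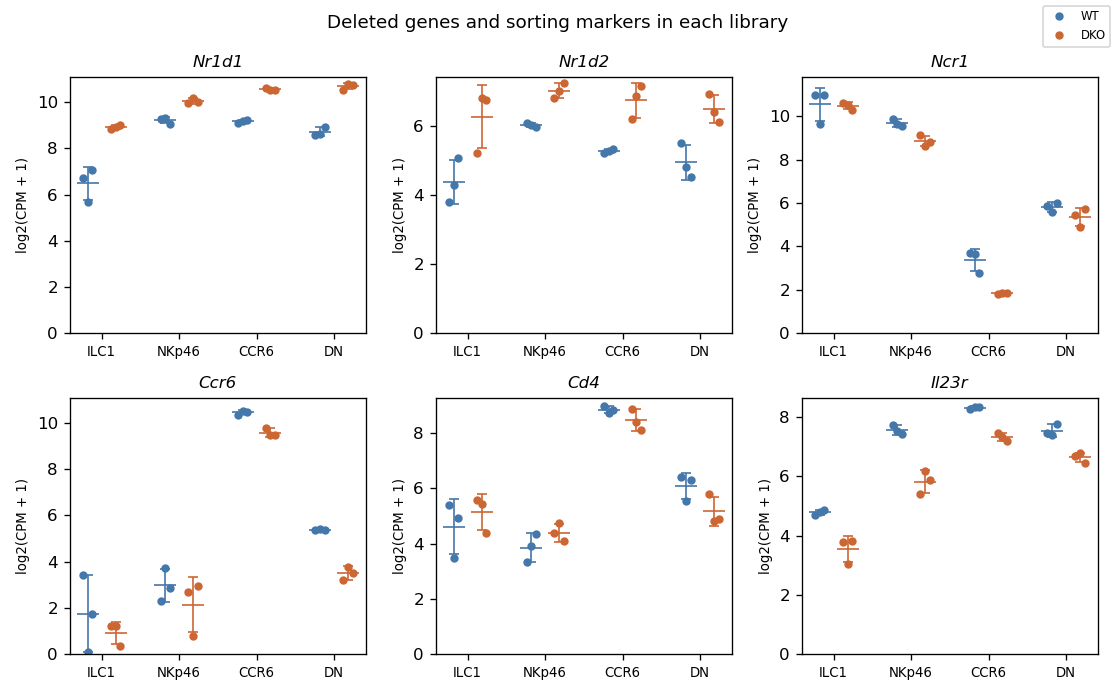
Levels of Nr1d1, Nr1d2, Ncr1, Ccr6, Cd4 and Il23r as log2(CPM + 1) in each of the 24 libraries, by sorted population, with WT and DKO side by side; points are libraries, dashes the mean of 3 and bars the SD. Nr1d1 lies higher in the DKO libraries of all 4 populations, and Il23r lies lower.

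The sorting markers set WT ILC1 and NKp46 cells apart from CCR6 and DN cells. Ncr1 measured 1614 ± 711 CPM in ILC1, 824 ± 103 in NKp46, 9.87 ± 3.41 in CCR6 and 55.5 ± 8.47 in DN. Ccr6 measured 1399.6 ± 86.7 CPM in CCR6, 40.7 ± 0.981 in DN, 7.54 ± 4.32 in NKp46 and 4.08 ± 5.11 in ILC1. Cd4 measured 462 ± 39.8 CPM in CCR6 and 69.1 ± 20.3 in DN, against 14.2 ± 5.21 in NKp46 and 27.1 ± 15.8 in ILC1.

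WT ILC1 were compared with WT NKp46 cells to see which genes set the populations apart without the deletion. ILC1 held more transcripts of cytotoxic and type 1 effector genes and fewer of the ILC3 programme. Ccl5, a chemokine of cytotoxic lymphocytes, was higher by 6.67 ± 0.38 (adjusted p = 1.4e-10), the lymphotactin gene Xcl1 by 4.97 ± 0.44, Prf1, which encodes perforin, by 2.98 ± 0.26, and Klrb1c, which encodes the NK1.1 receptor, by 2.86 ± 0.18. The natural killer receptor genes Klra3 and Klra6 had 0 counts in NKp46 and were at least 362-fold and at least 200.4-fold higher in ILC1, and Klre1 was higher by 8.12 ± 0.72. Eomes, a T-box factor of natural killer cells, had 0 counts in NKp46 and 0.980 ± 1.42 CPM in ILC1, at least 36.6-fold higher (adjusted p = 0.022). WT ILC1 library 3 carried this value, at 2.62 CPM against a mean of 0.161 in the other 2, and without it the call was lost (adjusted p = 0.085). Tbx21 at 1.28 ± 0.52 missed the threshold (adjusted p = 0.12). Of 36 type 1 and cytotoxic genes 25 were higher and 2 lower in ILC1 (29 and 2 adjusted over the list alone; adjusted p = 1.6e-04 with an estimated correlation). Of 20 ILC3 identity genes 12 were lower and 1 higher (13 and 1 adjusted over the list alone; adjusted p = 4.4e-06 with an estimated correlation). Among them were the interleukin 23 receptor gene Il23r at -2.82 ± 0.21, the interleukin 1 receptor gene Il1r1 at -4.40 ± 0.36 and lymphotoxin alpha (Lta) at -1.36 ± 0.15. Blk, a Src family kinase, and Ptprz1 and Ptprm, receptor tyrosine phosphatases, had 0 counts in ILC1 and were at least 404-fold, 279-fold and 171-fold lower. Nr1d1 was itself lower in ILC1 at -2.65 ± 0.22, as were the clock genes Ciart and Per3 at -1.89 ± 0.27 and -1.22 ± 0.29.

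Genes of other cell types also differed between these WT populations. Of 17 T cell genes 10 were higher and 1 lower in ILC1 (11 and 2 adjusted over the list alone; adjusted p = 0.0028 with an estimated correlation). Examples were the T cell receptor constant gene Trac at 89.0 ± 5.13 against 9.22 ± 4.81 CPM and the CD3 chain gene Cd3g at 101 ± 16.7 against 23.3 ± 2.47. Of 18 myeloid genes 5 were higher (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.030 with an estimated correlation). Among them were Itgax (CD11c) at 6.81 ± 0.85 and lysozyme 2 (Lyz2) at 3.41 ± 0.72. WT ILC1 library 2 held more myeloid transcripts than its replicates, by a median log2 ratio of 0.72 (S100a9 3.78), and 9.39% of its counts were ribosomal RNA. Of the NKp46 ILC3 genes 6 of 12 were higher in ILC1 and 1 lower (7 and 1 adjusted over the list alone). That list had adjusted p = 0.010 by camera with an estimated correlation. It shares members such as Klrk1 and Il2rb with the type 1 list, so its result is not separate from that of the type 1 list. Of 25 ribosomal protein genes 21 were higher (24 adjusted over the list alone, and adjusted p = 0.089 by camera with an estimated correlation). In all 2285 genes were called between WT ILC1 and WT NKp46, 1092 higher and 1193 lower in ILC1. The count was 459 when only these 2 groups entered the fit and 3581 with DESeq2.

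WT CCR6 cells carried an LTi-like programme and little of the type 1 programme of NKp46 cells. Of 16 LTi-like genes 13 were higher in CCR6 and 0 lower (13 and 0 adjusted over the list alone; adjusted p = 1.1e-06 with an estimated correlation). The MHC class II genes Cd74, H2-Aa and H2-Ab1 were higher by 5.22 ± 0.25, 5.29 ± 0.27 and 3.49 ± 0.26, Cd4 by 5.03 ± 0.47 and Ccr6 by 7.52 ± 0.84. Il17a was at 31.0 ± 13.4 against 0.205 ± 0.187 CPM, lymphotoxin beta (Ltb) was higher by 1.41 ± 0.12, and the cytokine gene Csf2 was lower at -3.03 ± 0.30; of ILC3 identity 9 of 20 genes were higher and 3 lower (12 and 4 adjusted over the list alone; adjusted p = 0.0015 with an estimated correlation). Of 36 type 1 and cytotoxic genes 28 were lower and 1 higher (31 and 1 adjusted over the list alone; adjusted p = 1.1e-06 with an estimated correlation). They included the cathepsin gene Ctsw at -5.17 ± 0.19, the granule protein gene Nkg7 at -5.12 ± 0.31, the chemokine receptor gene Cxcr3 at -3.01 ± 0.18 and Tbx21 at -6.05 ± 0.65. Of 12 NKp46 ILC3 genes 7 were lower (10 lower and 1 higher adjusted over the list alone). This list had adjusted p = 1.5e-06 by camera with an estimated correlation, and shares members such as Tbx21 with the type 1 list. The gut-homing receptor gene Ccr9 was lower at -3.50 ± 0.23, the amino acid transporter gene Slc6a20a at -8.64 ± 0.57 and the ribonucleotide reductase subunit gene Rrm2 at -3.38 ± 0.57 (-2.62 ± 0.53 without WT NKp46 library 1). Of 24 proliferation genes 10 were lower (14 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation). The neuronal adaptor gene Fez1 had 0 counts in NKp46 and was at least 291-fold higher in CCR6, and the checkpoint receptor gene Pdcd1 was higher by 5.97 ± 0.93. In all 1327 genes were called, 601 higher and 726 lower in CCR6, against 2286 when only these 2 groups entered the fit and 2176 with limma voom.

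WT DN cells had higher levels of T cell, ILC2, LTi-like and ribosomal protein genes than WT NKp46 cells. Of 17 T cell genes 15 were higher (17 adjusted over the list alone; adjusted p = 3.2e-08 with an estimated correlation). Examples were Cd3e at 574 ± 16.8 against 12.9 ± 2.52 CPM, Cd3g at 530.3 ± 30.0 against 23.3 ± 2.47, the gamma delta receptor constant gene Trdc at 274 ± 44.6 against 12.2 ± 3.39 and Trac at 225 ± 11.02 against 9.22 ± 4.81. Of 16 ILC2 genes 10 were higher (15 adjusted over the list alone; adjusted p = 1.9e-05 with an estimated correlation). They included Gata3, a transcription factor that ILC2 need, at 1.35 ± 0.16, the cytokine gene Il4 at 5.02 ± 0.67, the chemokine receptor gene Ccr8 at 3.97 ± 0.70 and Hs3st1, a heparan sulfate sulfotransferase, at 5.73 ± 1.08. Of 16 LTi-like genes 8 were higher (9 higher and 1 lower adjusted over the list alone; adjusted p = 9.7e-04 with an estimated correlation). Among them were Ccr7 at 5.27 ± 0.93 and Il17a at 5.55 ± 0.84. Type 1 genes went both ways, 8 higher and 8 lower of 36 (10 and 14 adjusted over the list alone): Ccl5 and granzyme A (Gzma) were higher by 4.92 ± 0.35 and 4.90 ± 0.52, and Klrk1, which encodes NKG2D, and Klrb1c were lower at -1.67 ± 0.22 and -1.80 ± 0.17. The integrin gene Itgae (CD103) was higher by 5.95 ± 0.74, the transcription factor gene Sox13 by 7.99 ± 1.23 and granzyme K (Gzmk) by 6.87 ± 1.19, while Ncr1, Slc6a20a and Klri2 were lower at -3.89 ± 0.31, -4.08 ± 0.45 and -3.45 ± 0.35. Of 12 NKp46 ILC3 genes 3 were lower and 1 higher (8 and 2 adjusted over the list alone; adjusted p = 9.7e-04 with an estimated correlation), and 24 of 25 ribosomal protein genes were higher (25 adjusted over the list alone; adjusted p = 0.0054 with an estimated correlation). In all 633 genes were called, 479 higher and 154 lower in DN. The count fell to 334, 379, 384, 415 and 416 without WT NKp46 library 2, WT DN library 2, WT NKp46 library 3, WT DN library 1 and WT NKp46 library 1, and rose to 989 when only these 2 groups entered the fit, 992 with limma voom, 998 without WT ILC1 library 2 and 1207 with DESeq2.

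**Figure D2:**
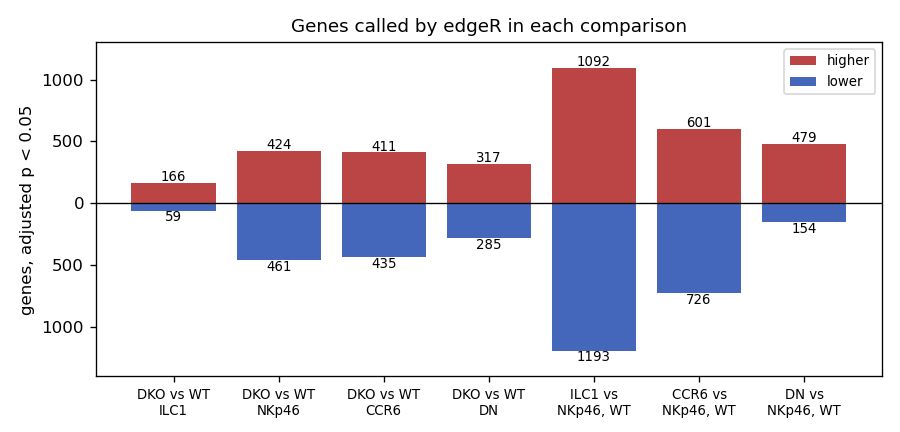
Genes called by edgeR at an adjusted p under 0.05 in each of the 7 comparisons, higher above the axis and lower below it, out of 21286 tested. Counts of DKO against WT run from 225 genes in ILC1 (166 and 59) to 885 in NKp46 (424 and 461).

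The effect of the DKO label was then asked in each population. The list of clock output genes rose in all 4. Of 12 clock output genes 4 rose in ILC1, 6 in NKp46, 7 in CCR6 and 6 in DN, and 0 fell (6, 7, 8 and 8 rose adjusted over the list alone). The list rose in each population with an estimated correlation too (adjusted p = 3.2e-04, 3.3e-05, 1.1e-06 and 4.8e-07). Ciart, a clock repressor, rose by 3.04 ± 0.28, 1.84 ± 0.26, 2.30 ± 0.26 and 2.69 ± 0.27 in ILC1, NKp46, CCR6 and DN, and Per3 by 2.07 ± 0.29, 2.03 ± 0.29, 3.25 ± 0.30 and 3.01 ± 0.30. Hlf, a PAR bZIP transcription factor, rose by 1.99 ± 0.34, 2.66 ± 0.34, 3.69 ± 0.36 and 2.67 ± 0.34, and Npas2 (chromosome 1, 39193731 to 39363236), a partner of BMAL1 that REV-ERBs repress, by 2.23 ± 0.48, 2.52 ± 0.47, 2.62 ± 0.47 and 2.88 ± 0.48. Bhlhe41 (chromosome 6, 145858243 to 145865558), a clock repressor also called DEC2, was 89.9 ± 25.2 against 1.36 ± 0.610 CPM in NKp46, 270.2 ± 19.8 against 0.722 ± 0.320 in CCR6 and 209.7 ± 9.85 against 0.538 ± 0.197 in DN. Its log2 fold changes there were 6.07 ± 0.51, 8.57 ± 0.56 and 8.60 ± 0.58 (adjusted p = 1.2e-07, 1.3e-09 and 3.3e-09). Of the 8 REV-ERB-repressed clock genes 1 rose and 1 fell in ILC1, 2 and 1 in NKp46, 3 and 1 in CCR6 and 3 and 1 in DN (1 and 1, 2 and 1, 3 and 1, 4 and 1 adjusted over the list alone). This list was called in DN (adjusted p = 0.014 with an estimated correlation) and in CCR6 (adjusted p = 0.13 with an estimated correlation).

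Il23r (chromosome 6, 67422932 to 67491855), which lets ILC3 respond to interleukin 23, fell by 1.28 ± 0.20, 1.73 ± 0.20, 0.98 ± 0.19 and 0.91 ± 0.19 in ILC1, NKp46, CCR6 and DN (adjusted p = 7.6e-04, 7.3e-06, 0.0026 and 0.0073). The cytokine gene Il17f (chromosome 1, 20777146 to 20790617) rose in 3 populations, from 4.19 ± 2.29 to 116 ± 69.4 CPM in NKp46, 85.5 ± 29.1 to 821 ± 97.9 in CCR6 and 23.7 ± 10.7 to 649.8 ± 214 in DN from WT to DKO, and missed the threshold in ILC1 at -1.55 ± 1.06 (adjusted p = 0.55). Ffar2, a receptor for short-chain fatty acids, fell by 0.95 ± 0.14, 1.02 ± 0.14, 1.19 ± 0.14 and 0.77 ± 0.14 in ILC1, NKp46, CCR6 and DN. The interferon-stimulated gene Oasl2 rose in all 4, by 1.43 ± 0.20, 1.54 ± 0.20, 1.62 ± 0.20 and 1.79 ± 0.20.

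Among genes with the smallest p-values that were called one way in all 4 populations was Gstm5, a glutathione transferase, which fell by 2.07 ± 0.19, 2.14 ± 0.19, 2.31 ± 0.19 and 2.15 ± 0.19. Ass1 (chromosome 2, 31470207 to 31520672), the argininosuccinate synthase of arginine synthesis, rose by 6.07 ± 0.57, 6.40 ± 0.57, 6.71 ± 0.57 and 5.23 ± 0.53. Tspan4, a tetraspanin gene, rose by 3.03 ± 0.28, 3.40 ± 0.28, 3.597 ± 0.29 and 4.04 ± 0.29. The adenylate kinase gene Ak7, Abi3bp and the predicted gene Gm36660 rose as well, by 1.99 (Abi3bp in ILC1) to 8.62 (Ak7 in CCR6). Crybb2 (chromosome 5, 113058258 to 113070117), a beta crystallin gene, had 0 counts in WT ILC1, NKp46 and DN and was at least 200.4-fold, 5335-fold and 11547-fold higher in DKO, and in CCR6 it was 325 ± 33.4 against 0.0633 ± 0.0900 CPM. Lpl (chromosome 8, 68880491 to 68907448), lipoprotein lipase, rose from 4.75 ± 2.24 to 35.5 ± 5.33 CPM in ILC1, 0.491 ± 0.415 to 113 ± 13.6 in NKp46, 0.869 ± 0.377 to 38.9 ± 10.8 in CCR6 and 0.231 ± 0.113 to 83.0 ± 1.37 in DN.

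**Figure D3:**
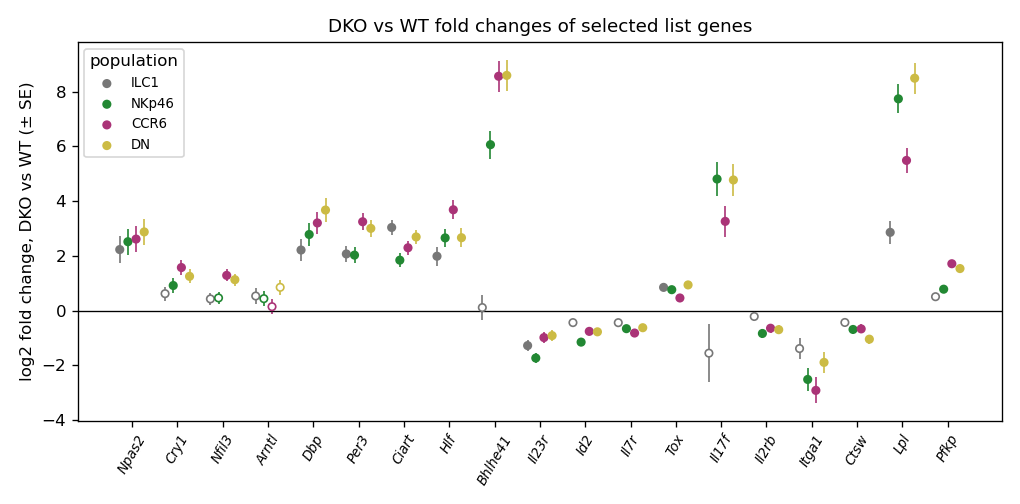
Log2 fold change of DKO against WT (y axis) with SE bars for genes of the fixed lists, chosen after their values were seen, in ILC1, NKp46, CCR6 and DN (3 libraries per group); filled points passed an adjusted p of 0.05 in edgeR and open points did not. Ciart, Per3 and Npas2 lie above 0 in all 4 populations, Il23r lies below 0, and Bhlhe41 lies at 0.11 in ILC1 and at 6.07 to 8.60 in the other 3.

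In ILC1, 166 genes were higher and 59 lower in DKO libraries. These 225 were the fewest to pass the adjusted threshold in edgeR, while the 2874 at an unadjusted p under 0.05 exceeded the 2803 in CCR6 and 2596 in DN. The growth factor signalling inhibitor gene Spry1 and the alarmin gene Il33 had 0 counts in WT and were at least 146-fold and 146-fold higher. The metalloproteinase inhibitor gene Timp3 rose from 0.0847 ± 0.147 to 8.05 ± 11.5 CPM (adjusted p = 0.036). DKO ILC1 library 1 held most of the Timp3 and Il33 counts, at 21.3 and 14.0 CPM against means of 1.42 and 0.930 in the other 2; without it Timp3 lost the call (3.61 ± 1.15, adjusted p = 0.22) and Il33 kept it (adjusted p = 0.0068). The Wnt ligand gene Wnt3, with 2 counts in WT, was at 12.2 ± 1.71 CPM in DKO (adjusted p = 2.3e-04). Eps8l3 fell by 4.19 ± 0.59, the actin cross-linker gene Actn2 by 2.76 ± 0.34 (2.10 ± 0.25 without WT ILC1 library 2), the scavenger receptor gene Stab2 by 2.80 ± 0.35 and Basp1 by 2.63 ± 0.27. Arginase 1 (Arg1) rose by 1.03 ± 0.15, the ILC development factor gene Tox by 0.85 ± 0.13, Lta by 0.93 ± 0.15, the oxysterol receptor gene Gpr183 by 0.73 ± 0.12 and the mitochondrial transcription factor gene Tfam by 0.85 ± 0.20. Of 36 type 1 and cytotoxic genes 0 were called (2 lower adjusted over the list alone), and the list lay lower in camera (adjusted p = 1.3e-04; adjusted p = 0.36 with an estimated correlation). Of 17 T cell genes Cd3g fell by 1.13 ± 0.27 and 0 rose (5 lower adjusted over the list alone; adjusted p = 0.19 with an estimated correlation), and of 20 glycolysis genes phosphofructokinase Pfkl rose by 0.80 ± 0.16 (2 higher adjusted over the list alone; adjusted p = 0.37 with an estimated correlation). Proliferation genes lay higher and myeloid genes lower in camera, each with 0 genes called over all genes or over the list alone (adjusted p = 0.48 and 0.36 with an estimated correlation). The myeloid list kept its camera call without WT ILC1 library 2 (adjusted p = 0.026) and lost it without WT ILC1 library 1 (0.12) or DKO ILC1 library 3 (0.18). The count of 225 depended on the libraries and the fit: it was 734 without WT ILC1 library 3, 149 without DKO ILC1 library 3, 12 when only these 2 groups entered the fit and 752 with DESeq2.

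In NKp46, DKO libraries had higher levels of the matrix protease gene Mmp9 and of clock output genes and lower levels of 4 genes of the NKp46 ILC3 list. Mmp9 (chromosome 2, 164940780 to 164955850), a gelatinase, rose from 7.66 ± 1.09 to 891 ± 90.8 CPM (6.86 ± 0.24; adjusted p = 3.0e-14), and the matrix protein gene Spon2 rose by 9.07 ± 1.27. Wnt3 and Nckap5 rose by 6.80 ± 0.92 and 8.39 ± 0.67, and Pik3r6, a regulatory subunit of PI3K gamma, had 0 counts in WT and was at least 341-fold higher. Ociad2 and the cation channel gene Trpc6 had 0 counts in DKO and were at least 154-fold and 139.8-fold lower, the potassium channel gene Kcnc1 fell by 5.62 ± 1.06, the calmodulin-binding gene Pcp4 fell by 7.56 ± 1.32 and the cell adhesion gene Dscam fell by 7.18 ± 0.99. Of 12 NKp46 ILC3 genes 4 fell and 0 rose (6 lower and 2 higher adjusted over the list alone), namely Klrb1b at -0.52 ± 0.09, the chemokine receptor gene Cxcr6 at -0.92 ± 0.19, the interleukin 2 receptor beta gene Il2rb at -0.83 ± 0.17 and the chemokine gene Ccl4 at -2.34 ± 0.62; the list missed the camera threshold (adjusted p = 0.075). Ncr1 lay at 464 ± 78.7 against 824 ± 103 CPM and missed the threshold (adjusted p = 0.11).

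Of 20 ILC3 identity genes 5 rose and 5 fell in NKp46 (7 and 9 adjusted over the list alone), among the latter Id2, a transcriptional regulator that all ILC need, at -1.15 ± 0.14. Of 36 type 1 and cytotoxic genes 3 rose and 10 fell (10 and 14 adjusted over the list alone): the integrin gene Itga1 (CD49a) fell by 2.52 ± 0.41, the transcription factor gene Irf8 by 1.19 ± 0.19 and the interleukin 18 receptor subunit gene Il18rap by 0.98 ± 0.17, and Ccl5 rose by 2.08 ± 0.31. Neither list passed camera (adjusted p = 0.31 and 0.31). Of 16 LTi-like genes 4 rose and 1 fell (5 and 3 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation). Examples were H2-Aa at 1.81 ± 0.24 and Ccr7 at 4.98 ± 0.92. Of 25 ribosomal protein genes 13 rose (21 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation), Rplp0 by 0.65 ± 0.14. Of 17 T cell genes 2 rose, the signalling adaptor gene Lat by 1.81 ± 0.16 and Trac by 1.28 ± 0.30 (5 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). Immunoglobulin mu (Ighm) rose by 1.78 ± 0.20, Blk fell by 3.61 ± 0.73, the platelet-derived growth factor receptor gene Pdgfrb rose by 2.63 ± 0.44, Tox rose by 0.77 ± 0.13 and Nt5e (CD73) fell by 1.24 ± 0.24. In all 885 genes were called, 424 higher and 461 lower. The count was 549, 571, 579 and 566 without WT NKp46 library 2, 3 or 1 and DKO NKp46 library 2, 1433 without WT ILC1 library 2 and 1716 with DESeq2.

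In CCR6, DKO libraries had higher levels of the clock output list, while the glycolysis, lipid, type 1 and inhibitory receptor lists were called by camera and lost the call with an estimated correlation. The angiopoietin-like gene Angptl2 rose by 8.03 ± 1.12, Cdcp1 by 7.89 ± 1.30, Pik3r6 by 7.63 ± 0.98, Plekhs1 by 7.51 ± 1.35 and Wnt3 by 7.42 ± 0.91. Fam189a1 and Fez1 had 0 counts in DKO and were at least 872-fold and 416-fold lower, the inducible nitric oxide synthase gene Nos2 fell by 7.70 ± 1.48, the calcium channel gene Cacna1g by 6.70 ± 1.07 and Eps8l3 by 5.62 ± 0.62. Of 20 glycolysis genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). Examples were phosphofructokinase Pfkp at 1.71 ± 0.14, the lactate transporter gene Slc16a3 at 3.09 ± 0.27 and the glucose transporter gene Slc2a3 at -1.15 ± 0.22. Of 22 lipid genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), Lpl by 5.49 ± 0.47 and the lipid droplet gene Plin2 by 1.56 ± 0.23, and of 18 cholesterol synthesis genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation). Examples were Cyp51 at -1.86 ± 0.34 and Sqle at -1.32 ± 0.25.

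Of 36 type 1 and cytotoxic genes 12 fell and 4 rose in CCR6 (17 and 6 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), Klrb1c at -2.32 ± 0.18 and Itga1 at -2.91 ± 0.48, while Tnf rose by 0.98 ± 0.18. Of 14 genes on the inhibitory receptor list 5 fell and 2 rose (8 and 2 adjusted over the list alone). The list had adjusted p = 0.13 by camera with an estimated correlation. Those that fell included Ctla4 at -3.06 ± 0.39 (-2.30 ± 0.30 without WT CCR6 library 1), Lag3 at -1.64 ± 0.19 and Cd96 at -1.09 ± 0.17. Those that rose included the ILC development factor gene Tox, at 0.463 ± 0.125. Of 16 LTi-like genes 3 fell and 1 rose (4 and 2 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), Cd74 at -1.21 ± 0.21 and H2-Ab1 at -1.22 ± 0.24. Of 20 ILC3 identity genes 7 fell and 4 rose (8 and 6 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), and of 12 NKp46 ILC3 genes 3 fell (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.099 with an estimated correlation). Ncr1 fell from 9.87 ± 3.41 to 2.59 ± 0.0426 CPM. Of 17 T cell genes 2 rose and 2 fell (2 and 3 adjusted over the list alone), Lat from 252 ± 40.2 to 2151 ± 56.2 CPM and Cd8a at -5.48 ± 1.05 (-4.71 ± 1.06 without WT CCR6 library 1). The survival gene Bcl2 fell by 0.88 ± 0.13, the NF-kB target genes Birc3, Traf1 and Icam1 by 1.07 ± 0.15, 0.93 ± 0.13 and 1.39 ± 0.24, and tetherin (Bst2) by 1.68 ± 0.20. Further lists called by camera in CCR6 had 1 member called over all genes and lost the call with an estimated correlation. Oxidative phosphorylation, proliferation and ribosomal proteins lay higher (1, 1 and 3 higher adjusted over the list alone; adjusted p = 0.53, 0.42 and 0.37 with an estimated correlation). B cell and plasma cell genes and myeloid genes lay lower (1 lower in each adjusted over the list alone; adjusted p = 0.21 and 0.33 with an estimated correlation). In all 846 genes were called, 411 higher and 435 lower, against 1632 when only these 2 groups entered the fit, 1739 with limma voom and 1327 with DESeq2.

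In DN, DKO libraries had higher levels of the clock output and lipid lists and lower levels of the T cell list, each also called with an estimated correlation. Plekhs1 had 0 counts in WT and was at least 865-fold higher, Timp3 rose by 11 ± 1.38, Spon2 by 8.54 ± 1.10 and Pik3r6 by 9.34 ± 1.14. Pcp4 fell by 6.67 ± 1.21, Kcnc1 by 6.59 ± 1.10, the muscle methyltransferase gene Smyd1 by 6.26 ± 1.11, Sox13 by 4.39 ± 1.00 and adrenomedullin (Adm) by 4.16 ± 0.95. Of 22 lipid genes 3 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0091 with an estimated correlation), namely Lpl at 8.495 ± 0.56, Plin2 at 1.40 ± 0.23 and the acyl-CoA dehydrogenase gene Acadvl at 0.55 ± 0.13. Of 20 glycolysis genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Among them were Pfkp at 1.54 ± 0.14, Pfkl at 1.17 ± 0.17 and enolase (Eno1) at 0.76 ± 0.16. Of 17 T cell genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation). Trdc fell by 1.85 ± 0.25, Cd3g by 1.60 ± 0.27 and Trbc1 by 0.65 ± 0.10, and Lat rose by 1.87 ± 0.16.

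Of 36 type 1 and cytotoxic genes 7 fell and 2 rose in DN (13 and 2 adjusted over the list alone; adjusted p = 0.087 with an estimated correlation). Examples were Klrb1c at -1.41 ± 0.17, Ctsw at -1.04 ± 0.16 and Itga1 at -1.89 ± 0.40, and Klrk1 higher by 1.15 ± 0.21. Of 16 ILC2 genes Gata3 fell by 0.68 ± 0.16 and 0 rose (1 lower adjusted over the list alone; adjusted p = 0.068 with an estimated correlation). Of 14 genes on the inhibitory receptor list 4 fell and 1 rose (4 and 1 adjusted over the list alone). The list had adjusted p = 0.16 by camera with an estimated correlation. Ctla4 at -2.03 ± 0.37 and Lag3 at -1.20 ± 0.18 were among those that fell. The 1 that rose was the ILC development factor gene Tox, at 0.94 ± 0.13. Of 21 TGF-beta and tissue residency genes Ccr9 fell by 1.15 ± 0.21 and the receptor gene Tgfbr1 rose by 0.87 ± 0.24 (6 lower and 2 higher adjusted over the list alone; adjusted p = 0.068 with an estimated correlation). Of 16 NF-kB targets Icam1 and Birc3 fell by 1.62 ± 0.24 and 0.56 ± 0.15 and Tnf rose by 0.78 ± 0.18 (5 lower and 2 higher adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Of 25 interferon-stimulated genes 2 fell, Isg20 at -1.07 ± 0.22 and Oas3 at -1.13 ± 0.29, and Oasl2 rose (3 lower and 1 higher adjusted over the list alone; adjusted p = 0.46 with an estimated correlation), and of 18 cholesterol synthesis genes 0 were called (2 lower and 1 higher adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). Of 20 ILC3 identity genes 6 fell and 3 rose (6 and 4 adjusted over the list alone), Id2 at -0.77 ± 0.14. The keratin gene Krt18 rose by 3.23 ± 0.63, and Blk and the B cell receptor gene Cd79b fell by 3.75 ± 0.68 and 1.25 ± 0.23. In all 602 genes were called, 317 higher and 285 lower. The count was 385 without DKO DN library 2, 934 without WT ILC1 library 2, 1199 when only these 2 groups entered the fit, 1079 with limma voom and 1057 with DESeq2.

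**Figure D4:**
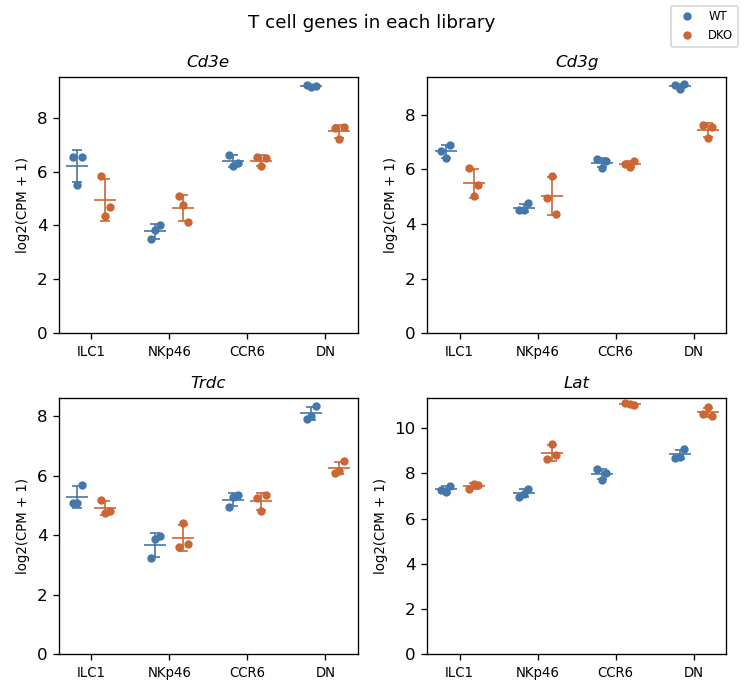
Levels of the T cell genes Cd3e, Cd3g, Trdc and Lat as log2(CPM + 1) in each library by population, with WT and DKO side by side; points are libraries, dashes the mean of 3 and bars the SD. In DN, Cd3e, Cd3g and Trdc lie lower in the DKO libraries and Lat lies higher.

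Calls overlapped between the populations. In all 1629 genes were called in at least 1 population, 80 of them in the same direction in all 4 (59 higher and 21 lower), 168 in 3, 329 in 2 and 1076 in 1, where the 24 genes called higher in one population and lower in another count once in each direction. CCR6 and DN shared 205 higher and 150 lower genes, where independent lists of these sizes would share 6.12 and 5.82. ILC1 and NKp46 shared 82 higher and 40 lower genes, against 3.31 and 1.28. Over the 6 pairs and both directions the shared counts were 17.4 to 36.7 times those of independent lists (Fisher's exact test, one-sided for more sharing, 12 tests, largest Benjamini-Hochberg adjusted p = 1.7e-25). The genotype comparisons share no libraries, though their animals may be shared. Fold changes of 10111 genes correlated across genes with Pearson r from 0.33 (ILC1 with CCR6) to 0.70 (CCR6 with DN) and Spearman correlations from 0.20 to 0.50, over genes that are not independent of each other. The count of 80 became 127 with DESeq2 and 53 at an adjusted p under 0.01. It was not taken with only the groups compared. ILC1 had 12 calls in that fit, so at most 12 genes could then be called in all 4.

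Whether the DKO effect differed between populations was tested on the difference itself. The effect was unlike among the 4 populations for 291 genes, and differed between NKp46 and ILC1 for 119 genes (47 higher and 72 lower in NKp46), NKp46 and CCR6 for 90 (47 and 43) and NKp46 and DN for 106 (75 and 31). Bhlhe41 and Lpl rose more in NKp46 than in ILC1, by 5.95 ± 0.67 and 4.88 ± 0.61, and Nr1d1 less, by -1.52 ± 0.29. The change of Ccl5 in NKp46 exceeded that in ILC1, CCR6 and DN by 2.60 ± 0.42, 3.39 ± 0.44 and 3.0 ± 0.42. H2-Aa differed by 1.83 ± 0.33 from ILC1 and 2.27 ± 0.33 from CCR6, and Tnf by -1.64 ± 0.25 from CCR6 and -1.44 ± 0.25 from DN. Cd3e, Cd3g, Trac and Trdc differed between NKp46 and DN by 2.62 ± 0.45, 2.16 ± 0.37, 2.88 ± 0.43 and 2.11 ± 0.35. These counts moved with 1 library: the ILC1 difference reached 544 genes without WT ILC1 library 3 and 65 to 77 without DKO ILC1 library 1, 2 or 3, WT NKp46 library 1, 2 or 3 or DKO NKp46 library 2, and the DN difference fell to 27 to 62 without any library of DKO NKp46, WT NKp46 or DKO DN or WT DN library 1 or 2. Without WT ILC1 library 2 the CCR6 and DN differences reached 232 and 338 and the test of any difference 561; the last was 614 without WT ILC1 library 3 and 186 without DKO CCR6 library 2. With only the groups compared the ILC1, CCR6 and DN differences were 10 (8 higher and 2 lower), 215 and 368, and with DESeq2 525, 331 and 473. The stricter filter gave 133 for ILC1, with 71 higher and 62 lower, and genotype with replicate number as a block gave 172 for DN.

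Whether the DKO effect in NKp46 followed the axis from ILC3 to ILC1 was asked with genes chosen from libraries of other populations. Of 1147 ILC3-high genes 126 fell and 65 rose in DKO NKp46, with a median log2 fold change of -0.23 (camera adjusted p = 0.0098; adjusted p = 0.22 with an estimated correlation). Of 1132 ILC1-high genes 63 rose and 54 fell, with a median of -0.01 (camera adjusted p = 0.34; 0.54 with an estimated correlation). With the 100 genes of smallest p each way the ILC1-high set had a median of 0.02 and the ILC3-high set of -0.24 (camera adjusted p = 0.037 for each), and both lost the call with an estimated correlation (adjusted p = 0.39 for each).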

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

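The tests of swapped genotype labels, of collection at different times of day, of the level of Thra, of fewer T cells in DN, of RNA from other cell types in WT ILC1 library 2, and of other splits and redrawn labels were chosen only after the results were seen, as was the choice of these 3 patterns.

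The effect of the DKO label differed between NKp46 and ILC1 in the edgeR test of the difference for a number of the named genes. On the log2 scale the effect in NKp46 minus that in ILC1, with both effects in brackets, was Spon2 9.09 (9.07 and -0.02), Il17f 6.36 (4.81 and -1.55), Bhlhe41 5.95 (6.07 and 0.11), Ccr7 5.26 (4.98 and -0.28), Lpl 4.88 (7.74 and 2.86), Gzma 2.98 (1.43 and -1.55) and Ccl5 2.60 (2.08 and -0.51). It was Cd3e 2.16 (0.96 and -1.21), H2-Aa 1.83 (1.81 and -0.03), Cd3g 1.69 (0.56 and -1.13), Lat 1.66 (1.81 and 0.15), Slc16a3 1.60 (1.79 and 0.19) and Ighm 1.54 (1.78 and 0.24). It was below 0 for Muc6 -9.60 (-4.22 and 5.38), Nt5e -1.73 (-1.24 and 0.49), Nr1d1 -1.52 (0.82 and 2.34) and Arg1 -1.10 (-0.07 and 1.03). Where a group held 3 counts or fewer no fold is given, and the difference had adjusted p = 0.0314 for Blk, 0.00148 for Il33, 0.00619 for Il17a, 0.0105 for Ociad2, 0.0401 for Kifc3 and 0.00666 for Pik3r6.

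Between NKp46 and CCR6 the effect of the DKO label differed as well. On the log2 scale the effect in NKp46 minus that in CCR6, with both effects in brackets, was Hpgds 5.48 (1.30 and -4.18), Pard3 4.77 (1.18 and -3.60), Ccl5 3.39 (2.08 and -1.31), H2-Aa 2.27 (1.81 and -0.46), Klrb1c 1.92 (-0.41 and -2.32) and Bst2 1.74 (0.06 and -1.68). It was Ighm 1.63 (1.78 and 0.15), Cd74 1.53 (0.33 and -1.21), Lag3 1.38 (-0.25 and -1.64), Cd160 1.17 (0.56 and -0.60), Ltb 1.01 (0.45 and -0.57) and Bcl2 0.97 (0.09 and -0.88). It was below 0 for Bmp4 -3.92 (-1.24 and 2.68), Ak7 -3.61 (5.01 and 8.62), Csf2 -2.30 (-0.83 and 1.47), Tnf -1.64 (-0.67 and 0.98), Ccr9 -1.61 (-1.06 and 0.54), Lat -1.28 (1.81 and 3.095) and Pfkp -0.93 (0.78 and 1.71). Where a group held 3 counts or fewer no fold is given, and the difference had adjusted p = 0.0299 for Fblim1, 0.0385 for Gzma, 0.00781 for Ociad2, 0.0287 for Ankrd35 and 0.00144 for Cd8b1.

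Between NKp46 and DN further effects of the DKO label differed. On the log2 scale the effect in NKp46 minus that in DN, with both effects in brackets, was Nckap5 4.74 (8.39 and 3.65), Samd3 4.25 (2.94 and -1.32), Zfp683 4.15 (1.06 and -3.09), Il4 3.72 (2.34 and -1.37), Ccl5 3.0 (2.08 and -0.92) and Trac 2.88 (1.28 and -1.60). It was Cd3e 2.62 (0.96 and -1.67), Ighm 2.24 (1.78 and -0.46), Cd3g 2.16 (0.56 and -1.60), Trdc 2.11 (0.26 and -1.85) and Rgs2 1.05 (0.59 and -0.47). It was below 0 for Klri2 -2.18 (2.02 and 4.195), Cd200r2 -2.14 (-0.52 and 1.62) and Tnf -1.44 (-0.67 and 0.78). Where a group held 3 counts or fewer no fold is given, and the difference had adjusted p = 0.0458 for Pros1 and 0.0367 for Ociad2.

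Nr1d1 and Nr1d2 were higher in the libraries labelled DKO, and swapped labels would lower the genes that REV-ERBs repress: Npas2, picked from a list of 8 of them, argues against a swap by rising 2.23 or more in each population, while in that list 1 to 3 genes rose and 1 fell per population and Arntl was called in none (0.14 to 0.85). For reads of Thra, which shares 263 exon bases with Nr1d1 on the other strand, the test set beforehand came out as that explanation needs: Nr1d1 minus Thra was -0.66 at its smallest, though 1.61 ± 0.32 in ILC1. A test by level, chosen after that and assuming even coverage, goes against it, since Nr1d1 gained at least 390 CPM while all of Thra reached 22.1 to 51.5 CPM in DKO libraries. Collection at different times of day stays open: it would move Npas2 and Dbp apart and both rose in 4 of 4 populations, but loss of repression would raise Npas2 at any time of day. Transcripts that keep undeleted exons and loss of repression of Nr1d1 and Nr1d2 by their own products remain open and were not tested, because counts per gene do not resolve exons and the labels do not name the deleted ones.

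T cell transcripts were lower in DKO DN libraries. A difference in library size is argued against, since 7 of 7 genes called lower stayed lower with all libraries thinned to the smallest (Cd3e -1.70, adjusted p = 0.0014). Fewer T cells among the sorted DKO DN cells would lower the list alike: the median of its 16 members of at least 5 CPM was -1.03, 6 of them lay over 2 SE from it, and Lat rose by 1.87. Fewer T cells may therefore account for part of the list and cannot be told apart here from lower transcription of Cd3e, Cd3g, Cd3d, Trac and Trdc in the DN cells, because counts per sample do not resolve cells and the labels do not say whether CD3-positive cells were gated out. Whether fewer T cells also lowered genes outside the list in DKO DN libraries, such as Sox13, was not tested. The genotype as a biological cause stays open.

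WT ILC1 library 2 stood apart from its replicates and had the lowest depth. Low depth as the whole cause is argued against, since its mean rank correlation with the other WT ILC1 libraries was 0.891 with all libraries thinned to one depth (0.892 before), and the lowest of the other 22 replicate pairs was 0.925. RNA from other cell types may add to it and stays open: B cell and plasma cell genes lay 0.915 above the other WT ILC1 libraries at the median (log2; Jchain 1.53), myeloid genes 0.72, with S100a9 at 3.78, and Col1a2 lay 1.95 above. Ribosomal RNA genes held 9.39% of its counts against 0.877% and 2.01%, and no biological explanation was tested.

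For each of the 7 comparisons of 3 with 3 libraries 1 of 10 splits, the real one, had the highest count, and 10 splits are too few for a share under 0.05. The real count and the highest other were 225 and 57 for DKO against WT in ILC1, 885 and 2 in NKp46, 846 and 1 in CCR6 and 602 and 0 in DN. For ILC1, CCR6 and DN against NKp46 in WT they were 2285 and 8, 1327 and 1, and 633 and 0. Every other split mixed libraries of the compared groups, which adds their difference to the spread. Low counts in those splits arise by construction, so they do not show what chance alone would call. With genotype labels redrawn 100 times within each population, 4, 2 and 3 draws, the real one included, gave as many genes for NKp46 minus ILC1, CCR6 and DN, and 2 for any difference among the populations. The draws mix WT and DKO libraries within a group, which adds the shared DKO effect to the spread, so they do not show whether chance can be excluded. The real counts were 119, 90, 106 and 291 and the highest others 1025, 1833, 1333 and 1600. Each other draw at or above the real count gave at least 1 compared population its real labels and another the mirrored ones. The contrast then subtracts a reversed effect, so a DKO effect shared by both populations counts as a difference by construction.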

How the results depend on the processing

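Chosen only after the data were seen were the runs with thinned counts, those without WT ILC1 library 2 in comparisons that do not use it, those with protein-coding genes alone, and those of the list and overlap results beyond the planned ones. None of the 291 calls of named genes reversed its direction in the alternatives it was counted in, while the median of the ILC1-high set, of -0.01, lay on either side of 0. Of these calls 291 were kept with RLE scaling, 285 with the replicate number as a block, 282 with counts thinned to the smallest library, 275 with limma voom, 267 without a filter and 249 with only the groups compared. With only the groups compared, ILC1 had fewer genes called in all than its 42 named calls, so most of those were lost. DESeq2 kept 287 of 287 it tested, the stricter filter 290 of 290 and protein-coding genes 279 of 283. Without WT ILC1 library 2, 288 of 291 were kept. Without 1 of the other libraries compared, 35 to 39 of 42 were kept in ILC1 (fewest without DKO library 3), 67 to 71 of 81 in NKp46 (WT library 1), 80 to 85 of 92 in CCR6 (WT library 2) and 61 to 66 of 76 in DN (DKO library 2). RLE scaling and thinning left every count of genes and the overlap within 1.5 times the reported value. WT and DKO libraries of one number correlated in their residuals at -0.047 to 0.258 (mean 0.098), with 7 of 12 pairs above 0.1, against a mean of -0.049 and 2 of 24 for unlike numbers. Residuals of a group sum to 0, so the values for unlike numbers largely follow from those for like numbers. They are not a separate comparison. A pairing by number in part of the libraries is not excluded. Within a genotype, 20 of 24 libraries correlated best with their own number in the other populations, out of 3 numbers to match. With the number as a block the counts were 222, 1023, 901 and 672 for DKO against WT in ILC1, NKp46, CCR6 and DN. With genotype and number together as the block, the difference between NKp46 and DN had 172 genes. The cause of the moves below was not tested, except that stricter thresholds call fewer genes by construction.

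For DKO against WT, DESeq2 called 752 genes in ILC1, 1716 in NKp46, 1327 in CCR6 and 1057 in DN. With only the groups compared the counts were 12 in ILC1, 1632 in CCR6 and 1199 in DN, and with limma voom 1739 in CCR6 and 1079 in DN. At an adjusted p under 0.01 they were 116, 415, 523 and 364, and at an adjusted p under 0.05 with an absolute log2 fold change above 1 they were 526 in NKp46, 559 in CCR6 and 398 in DN. For ILC1, CCR6 and DN against NKp46 in WT, an adjusted p under 0.01 gave 1208, 789 and 343, and only the groups compared 459, 2286 and 989. DESeq2 gave 3581 for ILC1 and 1207 for DN, limma voom 2176 for CCR6 and 992 for DN, and an absolute log2 fold change above 1 gave 1423 for ILC1 and 320 for DN.

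For the effect in NKp46 minus that in ILC1, CCR6 and DN, DESeq2 gave 525, 331 and 473, only the groups compared 10, 215 and 368, limma voom 52, 170 and 178, and an adjusted p under 0.01 gave 22, 43 and 23. No filter gave 296 for ILC1 and 178 for CCR6, the stricter filter 142 for CCR6 and 169 for DN, and protein-coding genes 59 for DN. Any difference among the 4 populations was called for 623 genes without a filter, 1058 with DESeq2 and 107 at an adjusted p under 0.01. Genes called one way in all 4 populations numbered 127 with DESeq2 and 53 at an adjusted p under 0.01. Of 100 list tests 37 were called by camera, 7 with an estimated correlation and 28 by fry. The ILC3-high median of -0.23 had adjusted p = 0.22 with an estimated correlation (from 0.0098), and the 100 ILC1-high genes of smallest p had a median of 0.02 (adjusted p = 0.037), which lost its call with an estimated correlation (adjusted p = 0.39), as did the 100 ILC3-high genes, at -0.24 (adjusted p = 0.39).

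With 1 library left out the counts for DKO against WT ran from 149 to 734 in ILC1, 549 to 1433 in NKp46, 588 to 1226 in CCR6 and 385 to 934 in DN. For ILC1, CCR6 and DN against NKp46 in WT they ran from 1534 to 3333, 925 to 1812 and 334 to 998, and for NKp46 minus ILC1, CCR6 and DN from 65 to 544, 60 to 232 and 27 to 338. Any difference ran from 186 to 614. Without WT ILC1 library 2 the counts were 1433 in NKp46 and 934 in DN, 998 for WT DN against WT NKp46, 232 and 338 for NKp46 minus CCR6 and DN, and 561 for any difference. Without WT ILC1 library 3 they were 734 in ILC1, 544 for NKp46 minus ILC1 and 614 for any difference. The report names the other libraries that moved a count by over 1.5 times. The median of the ILC1-high set ran from -0.06 to 0.03 and that of the ILC3-high set from -0.29 to -0.17.

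The share of higher calls moved by over 10 points in some runs. It was 73.8% in ILC1, 55.9% with DESeq2 and 91.7% with only the groups compared. For NKp46 minus ILC1 it was 39.5%, 53.4% with the stricter filter, 80.0% with only the groups compared, 29.1% without WT ILC1 library 1 and 63.6% at an adjusted p under 0.01. For NKp46 minus DN it was 70.8%, 55.8% without a filter, 58.0% without WT ILC1 library 2 and 60.7% and 59.7% without DKO NKp46 libraries 1 and 3. For NKp46 minus ILC1 the share thus lay on either side of 50%. Mean depth was lowest in DKO NKp46 (26.8 M) and WT ILC1 (29.0 M), and the smallest library was WT ILC1 library 2 (12.8 M). In simulated counts 38% of 2-fold changes were found in ILC1, 35% in NKp46, 50% in CCR6 and 47% in DN, which does not follow the order of the counts, since NKp46 had the most calls. The simulated dispersion of a gene was the same in all populations.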

Other observations

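No tests in this part were chosen after the results were seen. None of the 5 lists that follow passed camera at an adjusted p of 0.05 in a genotype comparison. By fry, apoptosis regulators lay lower in CCR6 and DN (adjusted p = 0.011 and 0.0064). The mixed test of fry, for moves in either direction, passed an adjusted p of 0.05 for apoptosis regulators in all 4 populations and for dissociation stress genes in NKp46, CCR6 and DN. It passed for mitophagy and mitochondrial genes in ILC1, CCR6 and DN, for epithelial genes in NKp46 and DN and for stromal and endothelial genes in NKp46. The mixed test passed for most of the lists tested in each population, so a pass is not particular to these lists. Of 12 stromal and endothelial genes 1 rose in each of NKp46, CCR6 and DN and 0 in ILC1, with equal counts adjusted over the list alone. Of 12 epithelial genes the keratin gene Krt18 rose by 2.34 ± 0.61 in CCR6 and 3.23 ± 0.63 in DN (adjusted over the list alone 1 in each, and in NKp46 1 higher and 2 lower). Of 17 apoptosis regulators 0 were called in ILC1, 1 fell in NKp46, 3 fell and 1 rose in CCR6 and 2 fell in DN (3 lower, 2 lower and 1 higher, 3 lower and 1 higher, and 2 lower adjusted over the list alone). Of 29 dissociation stress and immediate early genes 0 were called in ILC1, 4 rose and 3 fell in NKp46, 4 rose and 1 fell in CCR6 and 1 rose in DN (0, then 6 and 7, 6 and 4, and 2 and 4 higher and lower adjusted over the list alone). Of 18 mitophagy and mitochondrial genes 1 rose in ILC1, 0 in NKp46, 2 in CCR6 and 1 in DN, where 1 fell (2, 0, 2 and 1 higher, and 1 lower in CCR6 and in DN, adjusted over the list alone).

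Between the WT populations, camera called lists beyond those described in the comparisons, most of which lost the call with an estimated correlation. In ILC1 against NKp46, glycolysis had 5 of 20 genes lower and 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation). Inhibitory receptors had 6 of 14 higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation). Proliferation had 1 of 24 each way (1 each way adjusted over the list alone; adjusted p = 0.38 with an estimated correlation), and TGF-beta and tissue residency genes had 6 of 21 higher and 4 lower (9 and 4 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). Apoptosis regulators, with 4 of 17 higher, and REV-ERB-repressed clock genes, with 2 of 8 lower, kept the call (9 higher and 1 lower, and 2 lower, adjusted over the list alone; adjusted p = 8.0e-04 and 0.039 with an estimated correlation).

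In CCR6 against NKp46, inhibitory receptors had 6 of 14 lower and 3 higher (7 and 4 adjusted over the list alone; adjusted p = 0.080 with an estimated correlation), and T cell genes 5 of 17 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). TGF-beta and tissue residency genes had 6 of 21 lower and 4 higher (8 and 6 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). Ribosomal proteins had 2 of 25 higher, and glycolysis and epithelial genes 2 lower each, over all genes and adjusted over the list alone (adjusted p = 0.66, 0.58 and 0.19 with an estimated correlation). In DN against NKp46, interferon-stimulated genes had 5 of 25 higher (6 higher and 2 lower adjusted over the list alone; adjusted p = 0.37 with an estimated correlation) and clock output genes 1 of 12 lower (1 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Oxidative phosphorylation lay higher and proliferation lower in camera, with 0 genes called over all genes and 0 and 3 adjusted over the list alone (adjusted p = 0.53 and 0.25 with an estimated correlation).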
